A study of Homo sapiens with 263 samples.

How the data were processed

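Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out in LoVo, a human cell line from a colorectal adenocarcinoma. In this assay, DNA is cross-linked to the proteins bound to it, an antibody pulls down one protein, and the recovered DNA is sequenced. The series held 263 samples, of which 244 were antibody libraries with a peak list each and 19 were libraries made with nonspecific IgG. Per the labels, single-end reads came from an Illumina GAIIx lane or from multiplexed Illumina HiSeq lanes. The submitters' processing notes name CASAVA version 1.4, the aligner BWA without a version, the peak caller MACS version 1.4 and the genome build hg18. All coordinates below are in hg18, counted from 1.

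Peaks were called by the authors separately in each library, with MACS 1.4.0rc2, against an IgG library of the same batch set, per the file headers. These headers give a p cutoff of 1e-05, a band width of 300 bp, an effective genome of 2.75e+09 bp and at most 1 tag kept per position. The deposited fold enrichment of a peak is a ratio of its tags to the local expectation from the scaled IgG control, per the file headers. The deposited score of a peak is minus 10 times the log10 of the MACS p. The deposited false discovery rate is a percent, as the authors' caller wrote it. The deposited summit is a position, given by the authors' files as a distance from the peak start. Fold enrichment and score are the authors' own values per peak and were used only to filter or rank peaks within 1 list. The IgG libraries had no peak lists among the files analysed and entered only through these calls. Because 18 IgG libraries served 244 antibody libraries, lists called against the same IgG library share its chance values, and part of any similarity within a set may come from that sharing.

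Sequencing depth was taken from the tags that MACS kept after removing duplicates. It ranged from 180994 to 21595310 tags per antibody library and from 752623 to 11674904 per IgG library. Depth limits how many weak sites a list can hold, so absence from a list was not read as absence of binding. Percentages of peaks or sites carry 95% Wilson intervals, which cover counting error only.

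The target, batch, set, antibody host and quality call of each library came from the labels. Libraries were grouped by target, and 8 libraries whose labels named conflicting targets entered no comparison. The remaining 236 libraries covered 226 targets. Replicate numbers follow the order of deposition and were not used to pair libraries. The labels' batches and sets were used instead, in comparisons within sets and between batches. Nothing in the labels said that libraries of one target came from separate cultures. P-values of comparisons between libraries therefore measure only the spread between these samples, which may be technical. The tests against shifts and Fisher's exact tests count summits or sites of fixed lists. Their p-values cover the placement of summits in those lists and no spread between libraries. For the p-values across factors, each factor counted once, and factors assayed in the same set are not fully independent.

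The planned filter was a false discovery rate of 5% or less, the rule that the labels' peak numbers carry in their name. The deposited false discovery rate column did not give those numbers, matching 5 of 236 labels exactly with a median of 4 peaks left per library. A fold enrichment of 2 or more matched 204 of 236 labels exactly and 211 within 5 peaks, and was used in its place. All listed peaks, without a filter, matched 199 exactly, so the rule behind the labels is not known. Of 772633 listed peaks, 27765 lay under that minimum and 5393 lay outside chromosomes 1 to 22 and X and were left out. The share of peaks near a transcription start site (TSS) was taken from the labels, as the authors computed it. No gene annotation in the build of the files was used here, so regions are given by position alone.

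A consensus cohesin site was a group of RAD21 summits merged at 250 bp and seen in at least 2 of the 4 RAD21 libraries, and a consensus CTCF site one seen in at least 2 of the 3 CTCF libraries. Cohesin sites near a CTCF peak but not near a consensus CTCF site were left out of the comparison of CTCF-bound with CTCF-free sites. A summit was near a site within 500 bp. Chance levels came from moving every summit by 10 to 50 kb in a random direction, which keeps the density of each chromosome neighbourhood. There were 1000 such shifts per passed library, 200 per failed library, 200 for clusters and 50 for pairs of factors. Enrichment was the log2 of observed over shifted counts, each with 0.5 added. Clusters were summits chained at gaps of 500 bp or less. Recurrent regions were chained in the same way from failed libraries and had to be hit by at least 10% of them. When a failed library was scored, its own hit did not count towards that minimum.

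Group means were compared with 2-sided permutation tests of 100000 resamples, or with an exact permutation test where a group held fewer than 10 libraries, and again within each set with at least 3 libraries of each kind. Site classes were compared per factor with Fisher's exact test and over factors with a 2-sided sign-flip permutation test. Proximity was tested against the shifts, 2-sided for the passed factors and 1-sided for repeated targets and clusters. Co-binding within families was tested by permuting factor names, 1-sided, and again with the mean of each pair of sets removed and names permuted within sets. Benjamini-Hochberg adjustment covered the factors or targets of each comparison, with a threshold of 0.05. The smallest p these tests can give is 1e-05 for 100000 resamples, 0.002 for the 2-sided test against 1000 shifts and 0.00498 for 200 shifts.

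Comparisons, tests, most alternatives, 16 lists of factor families and the rule for naming items were fixed before the data were examined. The rule names CTCF, RAD21, SA1, SA2, CTCFL and the repeated targets. It adds the 5 highest and 5 lowest factors of each measure, the passed members of families with at least 2 of them, the 5 pairs with the highest ratio among those sharing at least 50 summits, the 3 failed libraries with the most peaks, and the 5 clusters and 5 recurrent regions with the most libraries. A few further factors are named beside these, and they were chosen after their values were seen. Alternatives covered distances, peak filters, the definition of cohesin sites, omission of single libraries and of UBP1 with ZNF281, and permutation within sets.

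Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The procedures were tested on simulated data. For cohesin proximity of the passed factors, 0 of 42 simulated libraries were called with no planted overlap and 42 of 42 with 5% of peaks planted at cohesin sites. Planted shares of 5%, 20% and 50% came back as 5.71%, 20.6% and 50.4%. For clusters, a planted share of 29.6% came back as 29.9%. In both simulations the other summits were placed at random along the chromosomes. With none planted, 0.775% lay near cohesin sites, against a mean of 1.39% for real shifted peaks. These simulations therefore do not measure false calls for summits gathered at promoters or accessible chromatin. With no difference, 6% of 200 simulated passed-failed comparisons and 4% of 200 simulated sign-flip tests reached a p of 0.05, and with a difference of 1 SD 100% of both did. For the comparison of cohesin site classes, a planted log2 ratio of -1 came back as -1.00, and for pairs of factors a planted 30% of shared summits came back as 30.1%. The family test within sets reached a p of 0.05 in 5.5% of 200 simulations with a set effect alone and in 100% with a family effect of 1 SD added.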

Results

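The series profiled DNA-binding proteins in LoVo cells, and its title asks whether they gather in dense clusters around sites of cohesin, the ring complex that holds DNA strands together. Of 236 antibody libraries with an assigned target, the labels' automated quality call passed 51 and failed 185. The passed libraries held 42 sequence-specific or associated factors with 1 library each, 3 libraries of CTCF, 4 of RAD21 and 1 each of CTCFL and SA1. CTCF is the zinc finger protein of insulators and chromatin loop anchors, RAD21 is the cohesin subunit that closes the ring, SA1 and SA2 are alternative cohesin subunits, and CTCFL is the CTCF paralogue normally made in testis. Failed libraries are described in the labels as control data. The libraries came from 3 batches split into 7 sets, and tags after duplicate removal ran from 971911 to 21595310 in passed and from 180994 to 17448601 in failed libraries. A value given for a single factor rests on 1 library, without a replicate.

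Passed libraries listed more peaks than failed ones. The passed factors with the most peaks were ZNF83 with 18092, TAL1, a regulator of blood cell formation, with 17363, the interferon-response factor IRF1 with 15980, the AP-1 subunit JUN with 14875 and the cell cycle regulator E2F3 with 13667. Those with the fewest were BCL6, a repressor of germinal centre B cells, with 663, the transcript cleavage factor PCF11 with 822, the E2F family repressor E2F8 with 989, the stem cell factor SOX2 with 1965 and UBP1, of the CP2 family, with 2061. Among failed libraries, ATF2 listed 26203 peaks, the forkhead protein FOXP1 19612 and ZNF217 12489, against a failed median of 753 and a passed median of 6942. Mean log10 peak number was 3.82 ± 0.399 (SD, n = 51) in passed and 2.89 ± 0.378 (SD, n = 185) in failed libraries. The difference of 0.926 had a permutation p of 1e-05, the smallest possible. Within the 7 sets it ran from 0.50 to 1.47, with exact or permutation p-values between 1e-05 and 0.00126. The quality call itself uses the number of peaks, so the comparison is descriptive.

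Binding near transcription start sites differed widely between factors. GMEB2, which binds glucocorticoid modulatory elements, had 87.6% of its peaks close to a TSS by the labels. ZNF280D had 85.6%, ZNF84 had 85.0%, and the CCAAT-box subunits NFYC and NFYA had 83.9% and 78.3%. The lowest shares were those of FOXA2, a pioneer factor of endoderm and gut, at 8.13%, the small MAF proteins MAFG at 11.9% and MAFK at 21.5%, JUN at 20.7% and the ETS protein ERM at 21.0%. The mean over passed libraries was 43.6 ± 22.9% (SD, n = 51), against 11.4 ± 10.2% (SD, n = 185) in failed ones. This difference of 32.2 percentage points had a permutation p of 1e-05, the smallest possible. The mean of the differences within sets was smaller, 19.9 points (permutation within sets, p = 1e-05). Batch 4 gave differences of 32.2 points in set 1 and 40.5 in set 2 (permutation p = 1e-05 each, the smallest possible) and 7.74 in set 3 (exact p = 0.533). Batch 5 gave 4.89 in set 1 (exact p = 0.116) and 41.7 in set 2 (permutation p = 1e-05). Batch 3 gave 3.27 in set 1 (exact p = 0.196) and 9.25 in set 2 (exact p = 0.033). The passed libraries of set 1 of batch 3 were CTCF, RAD21 and FOXA2, and those of set 1 of batch 5 were CTCFL, RAD21 and SA1. The difference passed the threshold in 4 of the 7 sets, one of them set 2 of batch 3. Of its 3 passed libraries, CTCF replicate 2 and RAD21 replicate 2 have label peak numbers that equal sums over libraries of several sets, and whether their TSS shares describe those sums too is not known; the quality call itself uses TSS proximity.

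The repeated CTCF and RAD21 libraries show how far different sets gave the same sites. The CTCF libraries listed 21904, 28679 and 30702 peaks, and the RAD21 libraries 11265, 19472, 48037 and 21946. Pairs of CTCF libraries shared 57.1 ± 1.53% of their merged summits (Jaccard index, SD over 3 pairs), and pairs of RAD21 libraries 35.3 ± 9.37% (SD over 6 pairs). Pairs of a CTCF and a RAD21 library shared 40.8 ± 7.16% (SD over 12 pairs). Unequal list lengths cap this index, so it reflects list length as well as agreement. The cap was lowest for the shortest and longest RAD21 lists, which shared 19.6%. Of the shorter list of each pair, RAD21 pairs shared 69.3 to 90.1% and CTCF pairs 76.6 to 87.1%. Pairs of a CTCF and a RAD21 library shared 61.6 to 84.6% of the shorter list. The mean index of same-target pairs exceeded that of different-target pairs by 0.0178, with an exact permutation p of 0.2 over 35 splits. With the 5000 highest-scoring peaks of each library the difference was 0.145 (exact permutation p = 0.0286). Without one of the CTCF libraries it lay between -0.0272 and -0.0174, where 15 splits allow no exact p below 0.0667, and without one of the RAD21 libraries between 0.0415 and 0.0812, where 20 splits allow none below 0.05.

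Cohesin subunits and CTCF lay at largely shared positions. Consensus cohesin sites numbered 22949, of which 8070 were seen in 2 RAD21 libraries, 6662 in 3 and 8217 in 4. Of these sites, 78.8% lay within 500 bp of a consensus CTCF site, and 73.3% of 24666 consensus CTCF sites lay near a cohesin site. SA1 had 79.0% of 11843 peaks (95% interval 78.3 to 79.7) near cohesin sites and 75.7% near CTCF sites. For CTCFL the shares were 81.4% of 11781 peaks (80.7 to 82.1) near cohesin and 90.5% near CTCF. SA2 did not pass the quality call, yet 60.7% of its 2715 peaks (58.8 to 62.5) lay near cohesin sites and 60.4% near CTCF sites. SA1, SA2 and CTCFL were all assayed in set 1 of batch 5 with RAD21 replicate 4. Carry-over of reads between libraries of this set was not tested. RAD21 replicate 3, with the longest list, had 45.4% of its peaks near CTCF sites, against 71.6 to 86.5% in the other RAD21 libraries.

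The same question was asked for 5 targets with a library in both batch 3 and batch 4. BARX1, a homeodomain protein of foregut development, shared 70 of its 429 batch 3 peaks with its batch 4 list, or 16.3% against 0.597% after shifting (shift permutation, adjusted p = 0.005). CAMTA1, a calmodulin-binding transcription activator, shared 3 of 255, or 1.18% against 0.100% (shift permutation, adjusted p = 0.00749). ATF7 shared 1 of 267 (shift permutation, adjusted p = 0.335). The circadian factor ARNTL shared 0 of 155 and HOXD11 shared 0 of 320 (shift permutation, adjusted p = 1 for both). ARNTL and BARX1 failed the quality call in batch 3 and passed it in batch 4. Both libraries of ATF7, CAMTA1 and HOXD11 failed. For HOXD11 the labels name the same antibody product but a rabbit host in batch 3 and a mouse host in batch 4. These p-values are 1-sided and come from 1000 shifts.

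Every one of the 42 passed factors lay near cohesin sites more often than its shifted peaks. The zinc finger protein ZNF281 was highest, with 58.3% of 7439 peaks (95% interval 57.2 to 59.4) within 500 bp of a cohesin site, followed by UBP1 with 49.1% of 2061 (46.9 to 51.3). Next came ZBTB10 at 21.3%, the Hedgehog pathway effector GLI2 at 21.2% and ZNF395 at 20.9%, an order that changed with the RAD21 libraries used (below). The lowest shares were those of MAFG at 5.11% (4.27 to 6.11), BCL6 at 6.03%, E2F8 at 6.98%, NFYA at 7.66% and the ETS protein ELF2 at 9.34%. The mean was 15.9 ± 9.50% (SD over 42 factors), or 14.03 ± 4.11% without ZNF281 and UBP1, against a mean of 1.39% for shifted peaks. Mean log2 enrichment was 3.35 ± 0.57 (SD over 42 factors), and each factor had an empirical p of 0.002, the smallest possible from 1000 shifts. At a false discovery rate of 1% or less 38 of 42 factors passed, and with RAD21 sites seen in all 4 libraries 40 did. Shifting does not keep summits at promoters, and the factors averaged 49.5% of peaks near a TSS. The test therefore cannot tell gathering at cohesin sites from a shared placement in promoters or accessible chromatin.

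Members of the families with at least 2 passed factors spread over this range. The homeodomain proteins HOXA4, HOXA5, HOXA6 and BARX1 had 15.2%, 13.6%, 13.2% and 15.3% of their peaks near cohesin sites. In the interferon pathway, STAT2 had 20.9% and IRF1 13.9%. The bZIP proteins JUNB, CREB1 and JUN had 17.0%, 12.1% and 9.84%, and the small MAF protein MAFK had 12.01%. SOX9 and SOX2 had 15.1% and 10.6%, E2F3 had 16.2%, and the bHLH proteins ARNTL and TAL1 had 16.8% and 15.8%. ERM had 12.1% and NFYC 12.4%. The other ZNF-named proteins were ZNF280D at 16.7%, ZNF12 at 16.7%, ZNF83 at 15.7%, ZNF143 at 15.5%, ZNF266 at 15.4%, ZNF84 at 13.0% and ZNF263 at 11.4%.

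Proximity to CTCF sites ranked the factors in a partly different order. ZNF281 and UBP1 led again, with 58.8% and 55.9% of their peaks near a consensus CTCF site, followed by ZNF395 with 26.1%, ZBTB10 with 21.4% and RELA, the NF-kappaB activator, with 21.1%. FOXA2 was lowest at 4.06%, below MAFG at 4.93%, ERM at 5.88%, BCL6 at 7.09% and E2F8 at 8.39%. The mean over the passed factors was 16.7 ± 10.4% (SD, n = 42). Cohesin sites were also built only from RAD21 libraries of other batches than the factor's own. The mean cohesin share was then lower, 9.51 ± 8.50% (SD, n = 42), with 50.3% for ZNF281 and 37.5% for UBP1. Fewer RAD21 libraries defined these sites, and raw shares also depend on the number of sites. Mean log2 enrichment over shifted peaks was 3.00 in this setting, against 3.35 with the main sites. ZNF395 of batch 5 followed at 16.9%, while ZBTB10 and GLI2 of batch 4 fell to 10.6% and 11.7%. The order below ZNF281 and UBP1 thus depended on which RAD21 libraries defined the sites. In this setting the sites for factors of batch 5 included the longest RAD21 list, and those for factors of batch 4 did not. Shares of factors from different batches were therefore measured against unlike sites. All 42 factors stayed above their shifts in that setting.

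**Figure D1:**
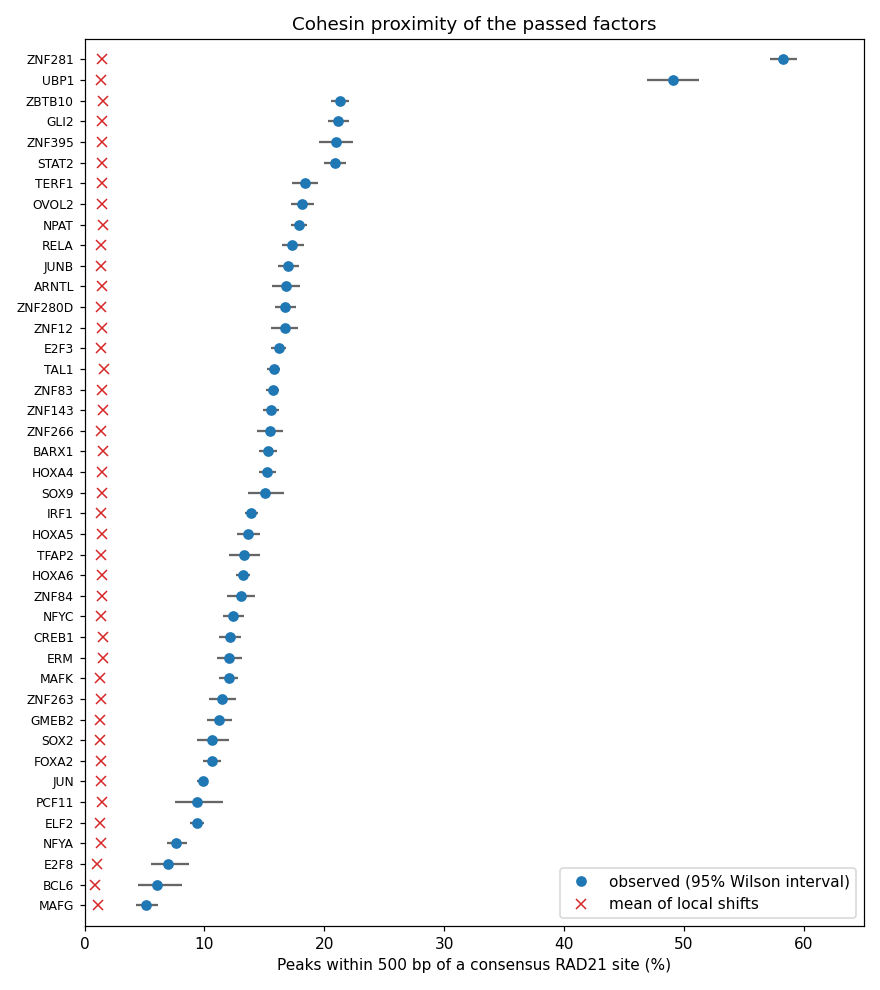
Percent of each passed factor's peaks within 500 bp of a consensus RAD21 site (points, with 95% Wilson intervals) and the mean percent after local shifts (crosses), for 42 factors. ZNF281 at 58.3% and UBP1 at 49.1% stand above the other 40 factors, the highest of which is at 21.3%, while the shifted means lie between 0.881 and 1.58%.

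Passed factors lay closer to cohesin sites than failed libraries, by an amount that varied between sets. Mean log2 enrichment at cohesin sites was 3.35 ± 0.57 (SD, n = 42) for passed factors and 1.42 ± 1.42 (SD, n = 184) for failed libraries. The failed libraries with the longest lists, ATF2, FOXP1 and ZNF217, had values of 1.82, 3.54 and 3.25. Failed libraries of batch 4 averaged 2.95 ± 0.92 (SD, n = 29), 2.30 ± 1.02 (SD, n = 32) and 2.47 ± 0.43 (SD, n = 7) in sets 1, 2 and 3. Those of batch 3 averaged 0.51 ± 0.74 (SD, n = 37) and 0.41 ± 0.81 (SD, n = 16), and those of batch 5 averaged 1.13 ± 0.93 (SD, n = 34) and 0.74 ± 1.78 (SD, n = 29).

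The passed-failed difference of 1.93 in log2 enrichment had a permutation p of 1e-05, the smallest possible. In batch 4 it was 0.28 in set 1 (permutation p = 0.32), 0.95 in set 2 (permutation p = 0.00061) and 2.05 in set 3 (exact p = 0.00303). The value of set 3 rests on 4 passed factors, and without UBP1 and ZNF281 it was 1.33 (exact p = 0.0278, the smallest possible with 36 splits). In batch 5 it was 2.60 in set 2 (permutation p = 8e-05). The other sets held fewer than 3 passed factors. Set 1 of batch 4, which holds passed libraries of GLI2, RELA, E2F3 and HOXA4, therefore did not show the difference at the threshold.

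**Figure D2:**
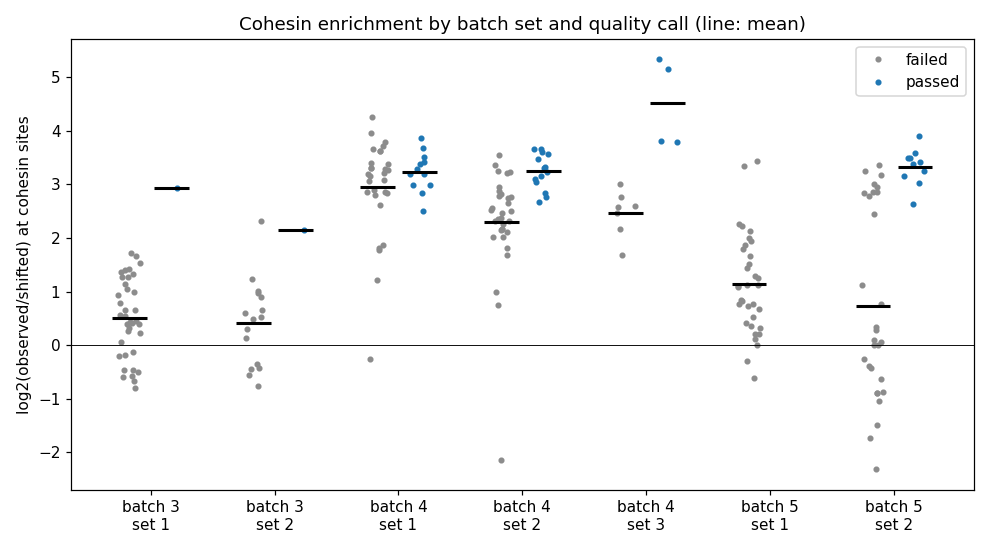
Log2 of observed over shifted peaks at cohesin sites for 226 libraries, by batch set and quality call, with 1 point per library and a line at each mean. Failed libraries of batch 4 average between 2.30 and 2.95, and those of batches 3 and 5 between 0.41 and 1.13.

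At the main setting, most summits of the passed factors fell into clusters. Clusters of at least 5 different factors numbered 18247 and held 62.1% of 283879 summits, against 0.924 ± 0.0398% (SD over 200 shifts) after shifting. The share of a factor's summits in such clusters was highest for RELA at 84.8%, GMEB2 and ZNF280D at 80.9% each, IRF1 at 76.2% and HOXA6 at 74.9%. It was lowest for MAFG at 11.8%, MAFK at 34.7%, FOXA2 at 37.5%, ZNF281 at 37.6% and UBP1 at 40.5%. MAFG and FOXA2 were the only passed factors of batch 3, each alone in its set. Since factors of 1 set shared more summits than factors of different sets (below), their low shares cannot be told apart from an effect of batch. ELF2 had the largest share of summits with no other factor in the cluster, 45.4%, and RELA the smallest, 3.74%. The 1-sided empirical p was 0.00498, the smallest possible with 200 shifts. Clusters holding at least 10 factors contained 37.2% of the summits. The share in clusters of 5 or more was 18.4% with the 500 highest-scoring peaks of each factor. At a false discovery rate of 1% or less it was 46.1%. Shifting does not keep summits at promoters or accessible chromatin. The test therefore cannot tell clustering of factors from accessible chromatin that yields reads with any antibody.

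The largest cluster held summits of 29 of the 42 factors, on chromosome 14 between 23653017 and 23654273. It included NFYA, NFYC, RELA, IRF1, GLI2, TAL1 and ZNF143 but not JUN, FOXA2, MAFG, MAFK or UBP1. Clusters of 28 factors lay on chromosome 7 between 6015037 and 6015565, on chromosome 11 between 116703653 and 116704194, on chromosome 16 between 30680617 and 30681366 and on chromosome 17 between 17435455 and 17436224. FOXA2, MAFG and UBP1 were absent from all 5 of these clusters, and for FOXA2 and MAFG the same limit of batch applies. ARNTL, BARX1, E2F3, GLI2, IRF1, JUNB and NPAT, an activator of histone genes, were named in the cluster on chromosome 14 and in those on chromosomes 7, 11, 16 and 17. None of these 5 clusters held a consensus cohesin or CTCF site.

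Cohesin sites were more frequent at clusters than at isolated summits. Of summits with a single factor, 8.65% (95% interval 8.41 to 8.90) had a cohesin site within 500 bp. The share was 17.4% for clusters of 2 to 4 factors, 20.05% for 5 to 9, 20.3% for 10 to 19 and 21.9% (18.6 to 25.7) for 20 or more. Shifted cohesin sites gave 1.23% at single summits, then 1.66%, 2.10%, 2.29% and, at the largest clusters, 2.49%. The ratio of observed to shifted shares was 7.004 at single summits, 10.49 at 2 to 4 factors, 9.55 at 5 to 9, 8.90 at 10 to 19 and 8.83 at 20 or more, so it did not rise with size beyond 2 to 4 factors. For CTCF sites the corresponding shares were 9.33% at single summits and 34.2% (30.2 to 38.4) at clusters of 20 or more factors. Clusters of 5 or more factors had a cohesin site in 20.2% of cases (19.6 to 20.8), and 16.1% of the 22949 cohesin sites lay at such a cluster.

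**Figure D3:**
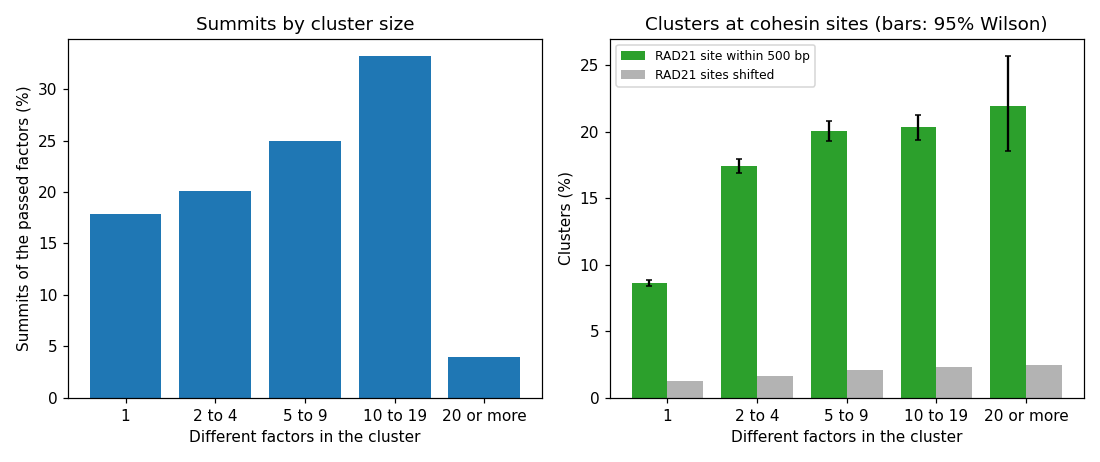
Left, percent of 283879 summits by the number of different factors in their cluster, and right, percent of clusters with a RAD21 site within 500 bp, with 95% Wilson intervals, beside the percent for shifted RAD21 sites. Isolated summits make up 17.8% of all summits and have a cohesin site in 8.65% of cases, against 20.05 to 21.9% for clusters of 5 factors or more.

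Cohesin sites with and without CTCF carried different factors. CTCF-bound sites lay within 500 bp of a consensus CTCF site, CTCF-free sites had no peak of any CTCF library within 500 bp, and the rest of the 22949 sites were in neither class. FOXA2 had a summit at 19.98% of the 2322 CTCF-free cohesin sites and at 1.19% of the 18081 CTCF-bound ones, a log2 ratio of -4.07. The ratio was -3.84 for ERM, -2.55 for BARX1, -2.39 for E2F8 and -2.32 for BCL6. In the opposite direction, UBP1 was at 5.34% of CTCF-bound and 0.646% of CTCF-free sites, a log2 ratio of 3.00, and ZNF281 at 22.3% and 7.02%, a log2 ratio of 1.66. HOXA4 had a log2 ratio of 0.48 (6.47% against 4.61%). ZNF395 and SOX9, at 0.15 and 0.11, did not pass the test.

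By Fisher's exact test with Benjamini-Hochberg adjustment, 34 of the 42 factors were less frequent at CTCF-bound sites and 3 more frequent. The 5 that did not pass were PCF11 at -0.71, MAFG at -0.55, CREB1 at 0.04, ZNF395 and SOX9. TAL1 was at 35.7% of CTCF-free and 8.22% of CTCF-bound sites, IRF1 at 28.4% and 6.27%, and ZNF83 at 24.98% and 10.7%. Any passed factor was present at 63.3% of CTCF-free sites (95% interval 61.3 to 65.2) and 50.9% of CTCF-bound sites (50.2 to 51.7). At least 5 factors were present at 38.6% (36.6 to 40.6) and 11.4% (10.9 to 11.8). The mean log2 ratio was -1.23 ± 1.21 (SD over 42 factors), with a sign-flip permutation p of 1e-05, the smallest possible. Among sites above the median RAD21 rank the mean was -0.51 (permutation p = 0.00129).

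**Figure D4:**
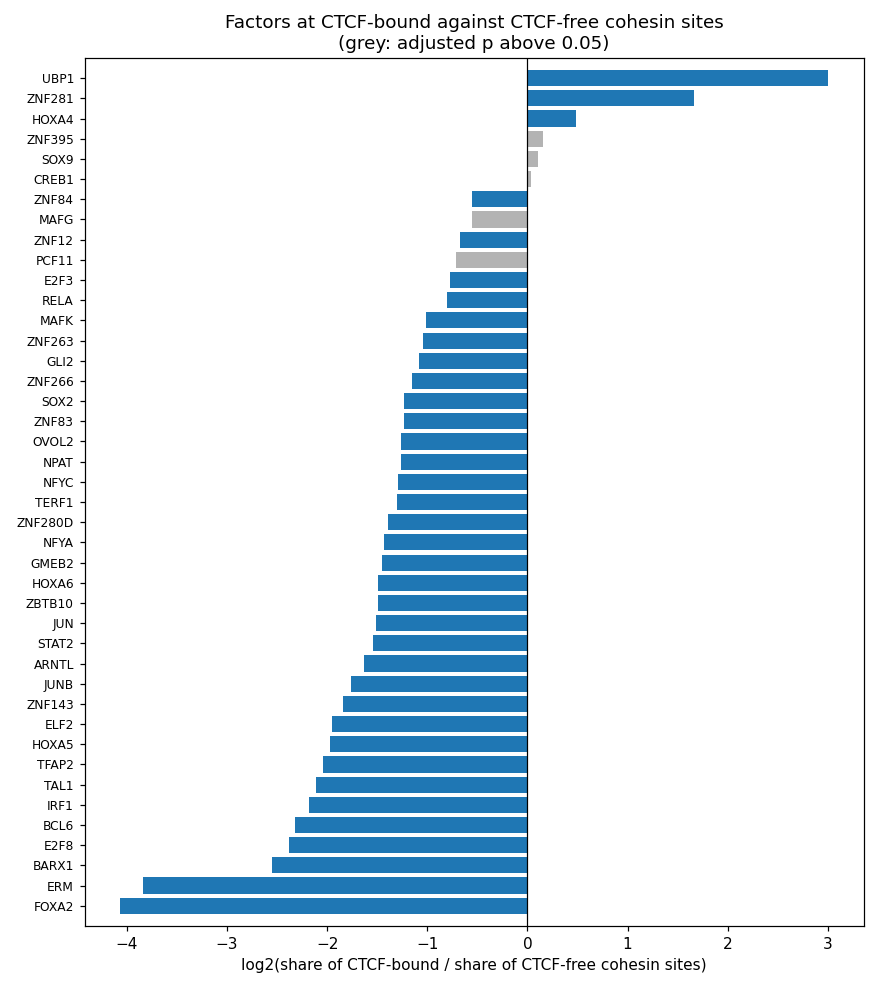
Log2 ratio of the share of CTCF-bound to the share of CTCF-free cohesin sites with a summit within 500 bp, for 42 factors, with factors above an adjusted p of 0.05 in grey. UBP1 at 3.00 and ZNF281 at 1.66 lie to the right, and FOXA2 at -4.07 is the lowest.

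Factors were also unevenly spread between the strongest and weakest cohesin sites. ZNF281 was present at 43.6% of the 4589 strongest sites and 6.30% of the 4589 weakest, a log2 ratio of 2.79, and UBP1 at 8.69% and 1.26%, a log2 ratio of 2.77. HOXA4 was the other factor more frequent at strong sites, with a ratio of 0.27, while MAFG at 0.39 and SOX9 at 0.32 did not pass the test. ERM was lowest at -3.22, followed by FOXA2 at -3.14, E2F8 at -2.98, NFYA at -2.40 and IRF1 at -1.92. In all, 34 factors were less frequent at strong sites and 3 more frequent by Fisher's exact test with Benjamini-Hochberg adjustment. A consensus CTCF site was near 95.8% of the strongest and 49.1% of the weakest sites.

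The mean log2 ratio of strong to weak sites was -1.0 ± 1.2 (SD over 42 factors), with a sign-flip permutation p of 2e-05. Ranking sites by score instead of fold enrichment turned the mean to 0.25 (permutation p = 0.139), and leaving out RAD21 replicate 3, the longest list, gave -0.19 (permutation p = 0.0963). The direction therefore depended on how strength was ranked. Sites above against below the median rank gave -0.64, and sites without RAD21 replicate 4 gave -0.52.

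Sharing of sites was compared between factors of one family and other factors. MAFG and MAFK, which bind the same recognition element, had the highest ratio of observed to shifted shared summits, a log2 of 7.46, with 61.1% of MAFG summits near a MAFK summit (1363 summits), although their libraries came from different batches. GMEB2 and JUNB followed at 6.24, ARNTL and NFYC at 6.11, GMEB2 and NFYC at 6.05, and ARNTL and JUNB at 6.05, and both libraries of each of these pairs came from 1 set. Among other families, NFYA and NFYC had 5.93, IRF1 and STAT2 5.10, ARNTL and TAL1 4.88, E2F3 and E2F8 4.55, ERM and ELF2 4.15, and SOX9 and SOX2 3.13. The 36 pairs of ZNF-named proteins averaged 5.04 ± 0.65 (SD), the 6 homeodomain pairs 4.43 ± 0.66 (SD), and the 3 pairs among CREB1, JUN and JUNB 4.0 ± 0.13 (SD).

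Same-family pairs averaged a log2 ratio of 4.91 ± 0.81 (SD, 52 pairs) and other pairs 4.30 ± 0.83 (SD, 809 pairs). The difference of 0.61 had a 1-sided permutation p of 0.00079. Pairs from 1 set averaged 5.01 ± 0.58 (SD, 208 pairs) and pairs from different sets 4.13 ± 0.80 (SD, 653 pairs). With the mean of each pair of sets removed and names permuted within sets, the family difference was 0.20 (permutation p = 0.0553), or 0.06 without MAFG and MAFK (permutation p = 0.273), so it did not pass the threshold once sets were taken into account. It was 0.23 among pairs of 1 set (33 family pairs, permutation p = 0.0933) and 0.19 among pairs of different sets (19 family pairs, permutation p = 0.135). Without removal of set means, pairs of different batches gave 0.56 (9 family pairs, permutation p = 0.0196), but -0.03 without MAFG and MAFK (8 family pairs, permutation p = 0.555). When the ZNF-named proteins were kept but not counted as a family, their pairs joined the other pairs. The difference was then 0.28 (16 family pairs, permutation p = 0.112). With all families and the 500 highest-scoring peaks of each factor it was 1.80.

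The share of promoter-proximal peaks was set against cohesin proximity. GMEB2, with 87.6% of its peaks near a TSS, had 11.2% near cohesin sites, and ZNF280D, with 85.6%, had 16.7%. FOXA2, with 8.13% near a TSS, had 10.6% near cohesin sites, and ZNF281, with 25.6%, had 58.3%. Across 42 factors Pearson's r was -0.05 (permutation p = 0.747, adjusted 0.934) and Spearman's rho 0.31 (permutation p = 0.0454, adjusted 0.0985), with 4 relations tested in this family. Without FOXA2 and MAFG, the factors farthest from the median TSS share, r was -0.15 (permutation p = 0.36). Within set 1 of batch 4, set 2 of batch 4 and set 2 of batch 5, r was 0.03, 0.33 and 0.52 (12, 14 and 10 factors, permutation p = 0.934, 0.246 and 0.125). Without UBP1 and ZNF281 it was 0.42 (permutation p = 0.00809) and rho 0.46 (permutation p = 0.00359), so the pooled r rests on these factors.

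Failed libraries repeatedly listed the same few regions. There were 45 regions hit by at least 19 of the 184 failed libraries, and none of the 45 held a consensus cohesin site. The most frequent lay on chromosome 11 between 84872065 and 84873278, with peaks in 37 failed libraries, of which 19 were in batch 3 and 17 in batch 5, and in the passed libraries of FOXA2, HOXA5, ZNF143 and 7 other ZNF-named proteins. A region on chromosome 9 between 92642730 and 92645273 had peaks in 30 failed libraries, 23 of them in batch 5, and in passed BARX1, HOXA6, ZNF280D and ZNF83. Chromosome 20 between 26136898 and 26138589 and chromosome 7 between 57552078 and 57554456 had 29 each, and chromosome 16 between 33780700 and 33782577 had 27. The regions on chromosomes 7 and 16 were also listed for BCL6, E2F8, SOX2, TERF1, the telomere repeat binding protein, and TFAP2. These libraries were all of set 2 of batch 4, shared 1 IgG library and were shallow, with 971911 to 2355631 tags. TAL1 and ELF2 of that set were also shallow, with 1784302 and 1619420 tags. TAL1 was listed for the region on chromosome 16 only and ELF2 for neither. The factors cannot be told apart here from depth and the shared IgG library.

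These 45 regions took 0.677 ± 0.816% (SD, n = 184) of the peaks of failed libraries and 0.187 ± 0.388% (SD, n = 42) of those of passed factors. The passed-failed difference in share, -0.490 percentage points, had a permutation p of 0.00031. Within sets 1, 2 and 3 of batch 4 it was -0.447 (permutation p = 0.00622), -0.251 (permutation p = 0.325) and -0.167 (exact p = 0.279), and within set 2 of batch 5 -0.965 (permutation p = 0.00264). The regions were chosen for recurring in failed libraries, and passed lists were longer. By number of regions hit, passed factors had 5.52 ± 6.29 (SD, n = 42) and failed libraries 5.02 ± 6.60 (SD, n = 184), which did not differ past the threshold (permutation p = 0.66). Among the top 100 peaks of each library the shares were 0.952 ± 1.99% and 2.45 ± 3.43% (permutation p = 0.00669). Chaining at 1000 bp gave -0.620 (permutation p = 0.0641), and a minimum of 5% of failed libraries gave -1.49 over 505 regions. A minimum of 20% left 1 region and a difference of 0.00493, because no failed library then keeps that region once its own hit is set aside.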

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

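Among the tests below, those of peaks carried over from other libraries and of tag numbers were chosen after the results were seen, and those of set-wide regions, list length and weak binding were written beforehand.

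The difference between passed and failed libraries was not the same in every set. In log2 enrichment at cohesin sites it was larger by 2.31 in set 2 of batch 5 than in set 1 of batch 4, the highest and lowest of 4 sets (interaction over these sets, permutation p = 0.00042). In log10 peak number it was larger by 0.972 in set 1 of batch 3 than in set 2 of batch 4, the extremes of 7 sets (interaction, permutation p = 1e-05, the smallest possible). In the share of peaks near a TSS it was larger by 38.5 percentage points in set 2 of batch 5 than in set 1 of batch 3, again the extremes of 7 sets (interaction, permutation p = 1e-05, the smallest possible). The tests concern any difference between sets, not these pairs of sets alone. They cannot separate the sets from the targets that passed in them. In set 1 of batch 3 the passed libraries were CTCF, RAD21 and FOXA2, with 14.6%, 7.96% and 8.13% of peaks near a TSS. Their mean was 10.2%, against 55.6% in set 2 of batch 5, where 10 factors passed besides CTCF. The failed means of these sets were 6.96% and 13.9%.

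Failed libraries of batch 4 lay near cohesin sites more than other failed libraries, with a mean log2 enrichment of 2.60 ± 0.97 (SD, n = 68) against 0.74 ± 1.16 (SD, n = 116). Longer peak lists do not account for all of this difference, though they may account for part. With the top 100 peaks of each library it was still 1.23 of 1.86 (permutation p = 1e-05, the smallest possible). Carry-over from CTCF or cohesin libraries of the same set cannot apply to sets 1 and 2, which held no such library. Within batch 4 their 61 failed libraries differed from the 7 of set 3 by only 0.14 (95% bootstrap interval -0.24 to 0.54). The level of batches 3 and 5 would have given -1.73. That level is not free of possible carry-over, since each set of those batches held a CTCF or cohesin library. Same-set carry-over stays open for set 3, which held RAD21 replicate 3 and had a mean of 2.47. Carry-over from RAD21 replicate 3 to the other sets of batch 4 was not tested. Weak true binding may be part of it, as summits of these libraries lay at clusters of the other batches with a mean log2 ratio of 2.51. Their mean log2 ratio of CTCF-bound to CTCF-free cohesin sites was -0.41 (sign-flip permutation p = 0.0168). CTCF-free sites are far fewer, so the 0.5 added to each count pulls this ratio below 0 in libraries with few summits at cohesin sites. It therefore cannot show a preference for CTCF-free sites. Accessible chromatin that yields reads with any antibody would give the same values and stays open.

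ZNF281 and UBP1, with 58.3% and 49.1% of peaks near cohesin sites, stood above the other 40 passed factors, and both were assayed in set 3 of batch 4 with RAD21 replicate 3. Regions that gather peaks in any library of that set are argued against, since 9 other libraries of the set had a mean log2 ratio of CTCF-bound to CTCF-free cohesin sites of -1.17. For UBP1, sites matched on RAD21 replicate 3 fold enrichment still had a log2 ratio of 1.03 (95% bootstrap interval 0.40 to 1.92). At CTCF sites matched on rank of fold enrichment, the ratio of sites with to without RAD21 was 0.34 (-0.12 to 0.97). This leaves CTCF reads open for UBP1. No set of batch 4 held a CTCF library, so such reads would have to come from another batch or a wrong label. For ZNF281 the matched RAD21 ratio was -0.16 (-0.40 to 0.10), so reads from that RAD21 library could account for it. Its matched CTCF ratio was 1.88 (1.55 to 2.30). Sites matched on fold enrichment may still differ in read number. The ratio of 1.03 thus argues against RAD21 reads alone for UBP1 only as far as fold enrichment tracks reads, which was not checked. The same limit holds for the ratio of 1.88 and CTCF reads alone for ZNF281. No biological explanation was tested for either factor, and binding of both at loop anchors remains an untested possibility.

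ARNTL and BARX1 failed in batch 3 and passed in batch 4. Fewer tags in batch 3 are argued against, since the batch 3 libraries had 1.95 and 1.77 times the tags of the batch 4 libraries. Differences in antibody lot, chromatin preparation or the quality of the pull-down stay open and could not be tested here, as no biological difference between the batches is given.

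Some peaks left out of the comparisons also lay near cohesin sites. Of 11832 peaks of passed factors under the fold minimum of 2, from 8 libraries, 16.0% (95% interval 15.4 to 16.7) lay within 500 bp of a cohesin site, against 1.56% after shifting. Among libraries whose labels named conflicting targets, unassigned replicate 6 had 9.80% of 2418 peaks near cohesin sites against 1.24% after shifting, and unassigned replicate 7 had 3.03% of 1452 against 1.21% (shift permutation p = 0.002 each, the smallest possible, adjusted 0.00533). Unassigned replicate 5 lay below its shifts, with 0.666% of 4207 peaks against 1.14% (shift permutation p = 0.002, adjusted 0.00533), and the other 5 did not pass the test.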

How the results depend on the processing

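Several alternatives were chosen after seeing the data. Among them were permutation within sets, use of all listed peaks and the 5% filter on the deposited false discovery rate. Others were the omission of UBP1 with ZNF281, of batch 4, of MAFG with MAFK and of libraries with label numbers above the listed peaks. The ZNF-named family label was dropped with its libraries kept. The rest were removal of set means in the family test, the other measures of recurrent regions and the restriction to clusters of at least 2 batches. Over 117 alternative values, 96 kept their direction and their side of the threshold or, for values without a test, stayed within the spread between factors or 1.5 times the count. All alternatives did so for peak number, TSS share, repeated targets, the count of factors near cohesin sites (38 to 42 of 42), the passed-failed difference in cohesin proximity (1.47 to 2.53), clusters and CTCF-bound against CTCF-free sites (-1.40 to -0.51). The passed-failed difference in log10 peak number was 2.40 at a false discovery rate of 1%. Where values moved and no reason is given, the cause was not tested.

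Replicate agreement was 0.145 with the top 5000 peaks, and omitting single CTCF or RAD21 libraries gave -0.0272 to 0.0812, with -0.0174, -0.0272 and -0.0268 without CTCF replicates 1, 2 and 3. Mean log2 enrichment of the passed factors was 3.98 at 250 bp, 2.60 at 1000 bp and 2.76 with RAD21 sites seen in all 4 libraries, and 2.96 to 3.36 without single RAD21 libraries. Strong against weak sites gave 0.25 by rank of score, -0.19 without RAD21 replicate 3 and -1.06 to -0.19 over omissions of single RAD21 libraries. Family co-binding was 0.28 with ZNF-named pairs counted as other pairs, and -0.0262 over pairs of different batches without MAFG and MAFK. With set means removed it was 0.20 over all pairs, 0.23 within sets, 0.19 between sets and 0.0584 without MAFG and MAFK. The correlation with TSS share was 0.42 without UBP1 and ZNF281. Recurrent regions numbered 505 at a minimum of 5% and 1 at 20%, where the difference of 0.00493 follows from setting aside each failed library's own hit, chaining at 1000 bp gave -0.620, and the number of regions hit gave a difference of 0.51.

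No paired analysis was possible because the labels carry no replicate numbers, and only 2 sets held both a CTCF and a RAD21 library. Blocking by set was possible, and its values are those of the permutations within sets. Depth limits the lists of the shallowest libraries, with 180994 tags in the lowest, so a factor missing from a cluster or site is not shown to be absent there. The permutation tests over factors treat 1 library as 1 factor, and antibody-specific effects cannot be separated from factor-specific ones.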

Other observations

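The test of family sites in failed libraries was chosen after the results were seen.

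Failed libraries varied in how far they shared summits with passed members of their family. NFYB, the third subunit of the CCAAT-binding complex, failed the quality call but had 16.6% of its 1910 peaks near an NFYA summit, and its log2 ratio of shared summits with passed members of its family exceeded that with other passed factors of the same sets by 1.84. STAT6 had 26.8% of its 1624 peaks near STAT2 summits and an excess of 0.98, while IRF8 and IRF3 of the same family had -0.17 and -0.86. GRHL2 had a difference of -2.28 with its passed relative UBP1. These 5 libraries were picked from 84 after their values were seen.

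As a hypothesis, failed libraries could hold sites of their own family in general. Over 84 failed libraries with a passed family member the mean excess was 0.0835 ± 0.684 (SD), and 51 of 84 were above 0 (sign-flip permutation p = 0.265). The test leaves the hypothesis undecided, since the mean is neither above nor below 0 beyond its spread.

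The labels of 8 libraries named conflicting targets. Unassigned replicates 1 to 4 had 1.93%, 0.879%, 0.493% and 1.51% of their peaks near cohesin sites, and unassigned replicates 5 and 8 had 0.666% and 0.960%. For unassigned replicate 1 the label gave 458 peaks and the list held 210, and for unassigned replicate 2 the label gave 210 and the list held 458. The same crossing occurred between unassigned replicates 5 and 6, with 2427 and 4234, and between unassigned replicates 7 and 8, with 844 and 1469.

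The label of CTCF replicate 2 gave 59462 peaks, which equals the sum of the 28717 listed for it and the 30745 listed for CTCF replicate 3. The label of RAD21 replicate 2 gave 89626, which equals the sum of the 19504, 48135 and 21987 listed for RAD21 replicates 2, 3 and 4. In the 4 RAD21 libraries, the gap of RAD21 replicate 3 in peak number was 0.710 of the range, under the critical value of 0.829.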
